A study of Mus musculus with 12 samples.

How the data were processed

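The samples are RNA libraries of lung Cx3cr1+ macrophages in 3 groups of 4, grouped by the treatment and genotype in their titles. Per the labels' protocols, cDNA was made with the SMART-Seq v4 kit, which amplifies full-length cDNA from very small inputs, libraries were made by Nextera XT tagmentation, and single-end reads were sequenced on a NovaSeq instrument. The kit does not mark strand, so reads from a gene and an antisense partner cannot be told apart. Per the submitters' processing notes, GSNAP, limma and Partek were used with the builds GRCm38 and mm10; versions and settings are not given in the sources used here. The series' design text describes another experiment (cultured alveolar epithelial cells) and was not used.

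The deposited table holds raw counts, whole numbers per Ensembl gene, made by the authors, for 52636 genes in 12 libraries; 11872 genes have no count in any library. Columns were matched to samples by the sample code in the labels. A deposited gene table gives symbols, exon coordinates and the exonic size of each gene. Chromosomes were taken from GENCODE vM21 (GRCm38). How reads matching several places were counted is not given in the sources used here. Gapdh, which has many pseudogenes, stood at 0 to 3.96 CPM, so genes with near-identical copies are uncertain, and Pcna is one such gene among those named. Replicates were compared before averaging: every pair of libraries differed by more than sampling noise. The lowest chi-square per degree of freedom of any pair was 21.5, so no pair was treated as 1 library deposited again. Separate libraries of 1 animal can also differ by more than sampling noise. The values therefore do not show that the libraries come from separate animals.

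CPM values (counts scaled to a common library size) were computed from the deposited counts with library sizes scaled by TMM. The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr by group (16679 genes kept), TMM scaling, robust dispersion and quasi-likelihood fits (glmQLFit, glmQLFTest) on all 12 libraries in 1 fit with group as the only term, and Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of its F statistic. The 95% interval for Il4ra uses 9 residual degrees of freedom. Differences of Il4ra between 4 and 4 libraries were also tested by an exact two-sided permutation test on log2 CPM, whose smallest possible p is 0.0286. A gene with 1 to 3 counts in a group is given as a ratio of pooled counts with an exact binomial interval, and no fold is given against a group with 0 counts. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

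Before the data were examined, 27 gene lists were fixed: 17 programmes (IL-4 receptor pathway, IL-4 and IL-13 induced genes, fibrosis-associated macrophage genes, secreted mediators, macrophage and monocyte identities, inflammation, interferon, MHC class II, cell cycle, metabolism, lysosome, complement and scavenger receptors) and 10 marker sets of other cells and stress. All 481 symbols were matched, 2 through an alias, and 465 were tested. Some genes are in more than 1 list, and several markers of other cells, such as Il7r and Cd24a, are also made by macrophages. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way. Each list also has counts of members adjusted over all genes and adjusted over the list alone.

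Named genes followed a rule fixed before the data were examined: Il4ra; the 5 highest and 5 lowest log2 fold changes among genes past the threshold with at least 10 CPM and no overlap of libraries; the 2 members of each programme list with the smallest p; and the 2 most abundant members of each list of other cells. Other genes named were chosen after their values were seen, including the genes named from the fit of 10 libraries, where the second part of the rule was applied again, and Gpnmb in the third comparison.

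The fit was tested on simulated counts with the real means, library sizes and dispersions of 16679 genes. The changed genes were drawn only from the more abundant of these, so the recovered shares do not cover genes at low levels. For bleomycin WT against saline WT, 54% of 100 genes changed 16-fold and 3% of 100 genes changed 4-fold were recovered, with 3 false calls among 60; the shares were 68% and 6% for bleomycin KO against bleomycin WT and 59% and 5% for bleomycin KO against saline WT. In simulated unchanged groups with 1 list raised 4-fold, camera called that list and 0 of the other 26. Genes were simulated independently of each other, so this cannot show how often camera calls lists whose genes move together. In the real first comparison the estimated correlation was 0.673 for the neutrophil list and 0.128 for the fibrosis-associated list. The common biological coefficient of variation was 0.862.

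Alternatives were DESeq2 size factors, upper-quartile scaling, no filter, a stricter filter of 10 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with and without sample quality weights, only the 8 libraries compared, a replicate block, each library left out, an adjusted p under 0.01 and a minimum absolute log2 fold change of 1. Added after seeing the data were fits without saline WT 2 and bleomycin WT 4, also without saline WT 1, and without bleomycin WT 2 and bleomycin KO 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

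Depth varied most within the saline group. The 60598 counts of saline WT 2 place its floor of 3 counts at 32.4 CPM, against 0.185 to 0.730 CPM in the other libraries, so levels under that in it rest on 0 to 2 counts and are not separated from 0. Relative to TMM, DESeq2 size factors moved the median log2 fold change of all genes by -0.18 in the first comparison and -0.16 in the third, and upper-quartile scaling by -0.31 and -0.22; in the second both moved it by less than 0.1. Directions are given on the TMM scale. No sequencing batch is given in the labels.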

Results

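Gene counts from bulk RNA sequencing were compared in Cx3cr1+ macrophages from mouse lung, in 3 groups of 4 libraries: saline-treated animals labelled wild type for the IL-4 receptor alpha chain (saline WT), bleomycin-treated animals labelled wild type (bleomycin WT), and bleomycin-treated animals labelled as having an Il4ra deletion (bleomycin KO). Bleomycin injures the lung and is widely used to induce fibrosis in mice. The labels do not say whether the 4 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. No saline group with the deletion was among the samples, so the deletion without injury was not analysed here.

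Total counts were 3534193, 60598, 10168525 and 6398289 in saline WT replicates 1 to 4. They were 9600870, 18051113, 12625799 and 9756454 in bleomycin WT and 16842991, 15472450, 13137078 and 8514384 in bleomycin KO. Saline WT 2 held counts for 4830 genes, against 17835 to 30283 in the other 11 libraries, and 3 counts in it are worth 32.4 CPM (counts scaled to a common library size). Bleomycin WT 4 had the lowest TMM scaling factor, 0.579, against 0.898 to 1.54 in the others. Its highest Spearman correlation with any other library was 0.730, while the other bleomycin libraries reached 0.939 to 0.986 (across genes, which are not independent replicates). Saline WT 1 reached 0.658 and saline WT 2 reached 0.498.

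**Figure D1:**
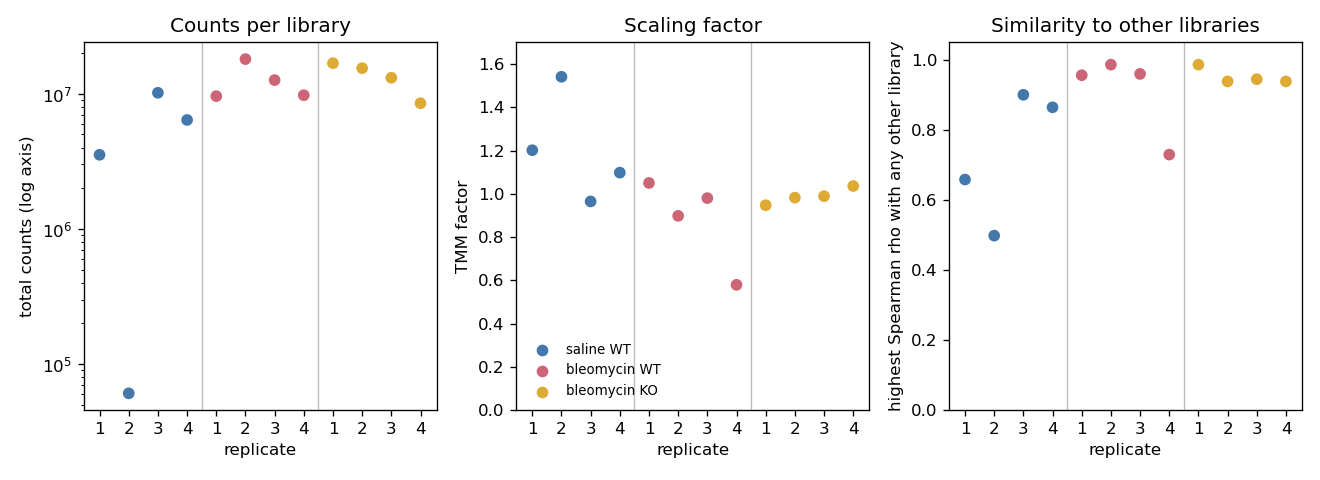
Total counts on a log axis, TMM scaling factor and the highest Spearman correlation with any other library for each of the 12 libraries, coloured by group; each point is 1 library. Saline WT 2 lies lowest in counts (60598) and bleomycin WT 4 lowest in scaling factor (0.579).

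Il4ra, which encodes the receptor chain shared by IL-4 and IL-13 signalling, was examined first because it checks the genotype labels. It was not lower in the libraries labelled KO. Its level was 332 ± 104 CPM (SD, n = 4) in bleomycin KO, 355 ± 203 CPM (SD, n = 4) in bleomycin WT and 177 ± 127 CPM (SD, n = 4) in saline WT. The 4 libraries labelled KO held 7540, 4207, 3042 and 3013 Il4ra counts. The log2 fold change of KO against WT was -0.09 (SE 0.58, 95% interval -1.41 to 1.23), with an edgeR adjusted p of 0.9998 and an exact two-sided permutation p of 0.943. The gene (ENSMUSG00000030748) lies on chromosome 7 from 125552120 to 125579474 in GRCm38 and is protein-coding. The counts are summed over the gene and include exons outside any deleted part, so an unlowered count does not by itself contradict a label. "KO" below means the libraries labelled KO.

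The first comparison asks what differed with bleomycin in the libraries labelled wild type. Some markers of other cell types also differed between these groups, as given below. Changes within macrophages therefore cannot be told apart from differences in which cells were collected. Library quality also went with treatment. Saline WT 1, 2 and 4 had the lowest total counts. The highest Spearman correlation with any other library was 0.498 to 0.900 in saline WT, and 0.939 to 0.986 in bleomycin libraries other than bleomycin WT 4. Effects of treatment cannot be fully told apart from these differences. Syngr1, Spp1, Gpnmb and Slc6a8 rose in bleomycin WT. For Syngr1, Spp1 and Gpnmb all 4 bleomycin WT libraries lay above all 4 saline libraries; Slc6a8 lay above saline WT 1, 3 and 4, while saline WT 2 is too shallow to show it at these levels. Spp1, which encodes the secreted matrix protein osteopontin, rose from 511 ± 447 to 13480 ± 10942 CPM (SD, n = 4 each), a log2 fold change of 4.71 (SE 0.70). Gpnmb, a transmembrane glycoprotein of lysosome-rich macrophages, rose from 127 ± 55.7 to 1350 ± 849 CPM (log2 fold change 3.39, SE 0.53). Syngr1, a synaptogyrin-family vesicle membrane protein, rose from 2.60 ± 2.18 to 222 ± 142 CPM (log2 fold change 6.04, SE 0.69). Slc6a8, the creatine transporter, had 651 counts in bleomycin WT and 2 in saline WT, a ratio of 154 with an exact interval of 42.4 to 1273 for counting error only.

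Their adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.00278 for Syngr1, 0.0433 for Spp1, and 0.0460 for both Gpnmb and Slc6a8. These 4 were the genes that passed among 16679 tested; 0 fell, and 2444 had an unadjusted p under 0.05, where chance gives 834. DESeq2 gave 512 genes (181 higher, 331 lower), limma-voom with quality weights 319 (150 higher, 169 lower), and limma-voom 6 (5 higher, 1 lower), of which 1 is among the 4. The count was 1 without saline WT 3, saline WT 4, bleomycin WT 2 or bleomycin WT 3, 2 without saline WT 1, saline WT 2 or any library labelled KO, and 11 without bleomycin WT 4. Without both saline WT 2 and bleomycin WT 4, an alternative chosen after seeing the data, 54 genes rose and 27 fell among 18812 tested. That alternative included the 4 genes named above, and all 81 genes had the same sign in the fit of 12 libraries. The 10 libraries are part of the 12, so this agreement in sign is not independent support.

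In that alternative of 10 libraries, the genes with the largest rises at 10 CPM or more, besides Slc6a8, Syngr1 and Spp1, were Plxna1 and Slc36a2. Plxna1, a semaphorin receptor subunit, rose from 2.59 ± 0.28 to 73.8 ± 59.6 CPM (SD, n = 3 each; log2 fold change 4.83). Slc36a2, a proton-coupled amino acid transporter, rose from 3.40 ± 2.89 to 66.2 ± 20.1 CPM (log2 fold change 4.28). The largest falls were in Ear1, Cyp4b1, S100a9, Inmt and Krt19. Of these, S100a9 is in the neutrophil list and Inmt in the fibroblast and smooth muscle list, while Ear1 and Krt19 are in the alveolar macrophage list. S100a9, a calcium-binding protein abundant in neutrophils, fell from 7116 ± 5439 to 442 ± 167 CPM (log2 fold change -4.01, edgeR adjusted p 0.0407), and Krt19, a keratin, fell from 238 ± 46.9 to 16.4 ± 9.03 CPM (log2 fold change -3.86, edgeR adjusted p 0.0154).

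Genes of the fibrosis-associated, lipid-handling macrophage list rose together. Of its 28 measured members 3 rose and 0 fell over all genes tested, and 16 rose when adjusted over the list alone; the median log2 fold change was 1.43 (camera adjusted p 1.2e-15, and adjusted p = 0.0205 with an estimated correlation). Besides Syngr1, Spp1 and Gpnmb, the list holds Msr1, a scavenger receptor with a log2 fold change of 2.47 (SE 0.46) that missed the threshold at an edgeR adjusted p of 0.101. In the 10 libraries 9 members rose, among them Msr1, Apoe, Trem2, Mmp14, Fabp5 and Il1rn. Apoe, the lipid carrier apolipoprotein E, rose there from 10131 ± 3549 to 32164 ± 6055 CPM (SD, n = 3 each), and Trem2, a lipid-sensing receptor, from 130 ± 54.2 to 527 ± 129 CPM.

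Secreted profibrotic and tissue-repair mediators also rose as a list. Of 25 measured members 1 rose and 0 fell over all genes, while 15 rose and 1 fell when adjusted over the list alone, with a median log2 fold change of 1.61 (camera adjusted p 7.4e-09, and adjusted p = 0.0205 with an estimated correlation). Spp1 is in this list too. Mmp12, the macrophage elastase, had 2460 ± 1677 against 222 ± 197 CPM (SD, n = 4 each; log2 fold change 3.44) and did not pass (edgeR adjusted p 0.101).

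Lysosomal genes passed as a list with the preset correlation and with fry, and not with an estimated correlation in the 12 libraries. Of 30 measured members 0 passed over all genes and 11 rose when adjusted over the list alone, with a median log2 fold change of 0.96 (camera adjusted p 5.1e-09, and adjusted p = 0.107 with an estimated correlation). Without saline WT 2 and bleomycin WT 4 the list also passed with an estimated correlation (adjusted p = 0.0298), and 5 members rose: Ctsd, Ctsb, Lamp1, Tpp1 and Ctss. Ctsd, the aspartic protease cathepsin D, was then 9476 ± 1970 against 2180 ± 155 CPM (SD, n = 3 each; log2 fold change 2.12, edgeR adjusted p 0.00159). In the 12 libraries Ctsd had a log2 fold change of 2.17 and Lamp1, a lysosomal membrane protein, of 2.22, each with an edgeR adjusted p of 0.0853.

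Cell cycle genes had a median log2 fold change of 1.01 over 30 members, of which 28 were higher and 0 passed over all genes or over the list alone (camera adjusted p 0.000275, and adjusted p = 0.389 with an estimated correlation). In the 10 libraries 13 members rose when adjusted over the list alone, and the list passed with an estimated correlation (adjusted p = 0.0278). Mki67, a marker of proliferating cells, was 63.5 ± 37.1 against 14.8 ± 13.6 CPM (SD, n = 4 each) in the 12 libraries, with an edgeR adjusted p of 0.267, and Kif20a, a mitotic kinesin, was 67.1 ± 38.9 against 13.01 ± 10.56 CPM.

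Genes induced by IL-4 and IL-13 passed with the preset correlation and not with an estimated one. Over 26 members, 0 passed over all genes and 1 rose when adjusted over the list alone, with a median log2 fold change of 0.49 (camera adjusted p 0.0297, and adjusted p = 0.378 with an estimated correlation). Without saline WT 2 and bleomycin WT 4 the list did not pass with the preset correlation (median 0.28, camera adjusted p 0.0597). Arg1, arginase 1, a widely used marker of alternative activation, was 380 ± 240 CPM in bleomycin WT and 7.88 ± 9.68 CPM in saline WT (SD, n = 4 each; log2 fold change 5.32, SE 0.93, edgeR adjusted p 0.0853), and all 4 bleomycin WT libraries lay above all 4 saline libraries. Rnase2a had 96 counts in bleomycin WT and 0 in saline WT, and bleomycin WT 4 also held 0. Components of the IL-4 receptor pathway without Il4ra did not pass as a list (median 0.50 over 12 members, camera adjusted p 0.173); the feedback inhibitor Socs3 was 518 ± 185 against 183 ± 65.4 CPM (edgeR adjusted p 0.219).

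Among the metabolic lists, cholesterol biosynthesis (median 0.74 over 23 members, camera adjusted p 0.0265), fatty acid oxidation (median 0.65 over 21 members, camera adjusted p 0.0233) and glycolysis and hypoxia response (median 0.45 over 23 members, camera adjusted p 0.0369) were higher with the preset correlation. With an estimated correlation none passed (adjusted p = 0.281, 0.251 and 0.598). Without saline WT 2 and bleomycin WT 4, glycolysis and hypoxia response no longer passed with the preset correlation (camera adjusted p 0.0590). Cholesterol biosynthesis and fatty acid oxidation still did (camera adjusted p 0.00122 and 0.00530). Hk2, hexokinase 2, was 231 ± 310 against 20.05 ± 15.85 CPM, where bleomycin WT 4 alone held 694 CPM.

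Monocyte and alveolar macrophage genes were lower in bleomycin WT as lists with the preset correlation. Non-classical monocyte genes had a median log2 fold change of -1.66, with 11 of 19 members lower when adjusted over the list alone (camera adjusted p 6.2e-10, and adjusted p = 0.107 with an estimated correlation). Adgre4, an adhesion receptor of these monocytes, was 28.1 ± 12.2 against 239 ± 209 CPM. Classical monocyte genes had a median of -0.48 (camera adjusted p 0.00195, and adjusted p = 0.389 with an estimated correlation), and Plac8 was 38.8 ± 18.3 against 323 ± 256 CPM with an edgeR adjusted p of 0.101. In that list 6 members were lower and 2 higher when adjusted over the list alone. Alveolar macrophage identity genes had a median of -0.68 over 27 members (camera adjusted p 0.00925, and adjusted p = 0.398 with an estimated correlation). They were split, with 5 members lower and 4 higher when adjusted over the list alone. Krt79 was 4.78 ± 4.19 against 123 ± 58.1 CPM. Without saline WT 2 and bleomycin WT 4, 9 members of the alveolar macrophage list were lower and 2 higher over the list alone. The median there was -0.85 (camera adjusted p 2.7e-05, and adjusted p = 0.0922 with an estimated correlation).

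The other programme lists did not pass. Interstitial macrophage identity had a median of 0.23, although camera placed it on the lower side (adjusted p 0.546); Cd163, a haemoglobin scavenger receptor, was 19.5 ± 9.84 against 134 ± 45.1 CPM with all 4 bleomycin WT libraries below all 4 saline libraries (edgeR adjusted p 0.201). Complement and scavenger receptors had a median of 0.89 (camera adjusted p 0.0590), inflammatory cytokines and chemokines of 0.20 (0.444), interferon-stimulated genes of 0.04 (0.989) and MHC class II presentation of 0.01 (0.524). Camera placed the last pair on the lower side although their medians were above 0.

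Markers of other cell types moved with the same contrast. The neutrophil list had a median of -3.25, with 11 of 12 members lower when adjusted over the list alone (camera adjusted p 9.4e-10, and adjusted p = 0.195 with an estimated correlation). S100a9 was 1298, 1989, 12140 and 7791 CPM in saline WT 1 to 4 and at most 582 CPM in any bleomycin WT library. S100a8 was 4884 ± 4949 CPM in saline WT and 289 ± 178 CPM in bleomycin WT. Lung epithelium (median -1.51, camera adjusted p 0.000275), endothelium (median -1.66, 0.00198) and erythroid and platelet genes (median -1.90 over 3 members, 0.0157) were lower, and T and NK cell genes higher (median 0.78, 0.0290); with an estimated correlation none passed (adjusted p = 0.251, 0.230, 0.120 and 0.389). The most abundant endothelial members went the other way: Calcrl was 151 ± 218 against 45.00 ± 34.33 CPM and Ptprb 60.8 ± 107 against 32.5 ± 16.4 CPM, both with their highest value in bleomycin WT 4. Without saline WT 2 and bleomycin WT 4 all 12 measured endothelial members, these included, were lower. Sftpc, surfactant protein C of alveolar epithelium, was 1182 ± 273 CPM in saline WT and 274 ± 245 CPM in bleomycin WT. Il7r was 31.2 ± 7.40 CPM in saline WT and 134 ± 25.5 CPM in bleomycin WT.

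The remaining cell-type lists did not pass: eosinophil, basophil and mast cell genes (median -1.26, camera adjusted p 0.136), dendritic cell genes (-0.31, 0.257), B and plasma cell genes (0.16, 0.989), fibroblast and smooth muscle genes (-0.08, 0.524) and dissociation and stress genes (-0.05, 0.411). Camera placed the B and plasma cell list on the lower side although its median was above 0. Hdc was 750 ± 862 CPM in saline WT and 254 ± 310 CPM in bleomycin WT, Ccr7 248 ± 231 and 239 ± 48.3 CPM, Cd22 44.6 ± 30.7 and 116 ± 79.3 CPM, Col3a1 15.8 ± 19.0 and 116 ± 25.0 CPM, and Junb 2819 ± 1393 and 3841 ± 1001 CPM.

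**Figure D2:**
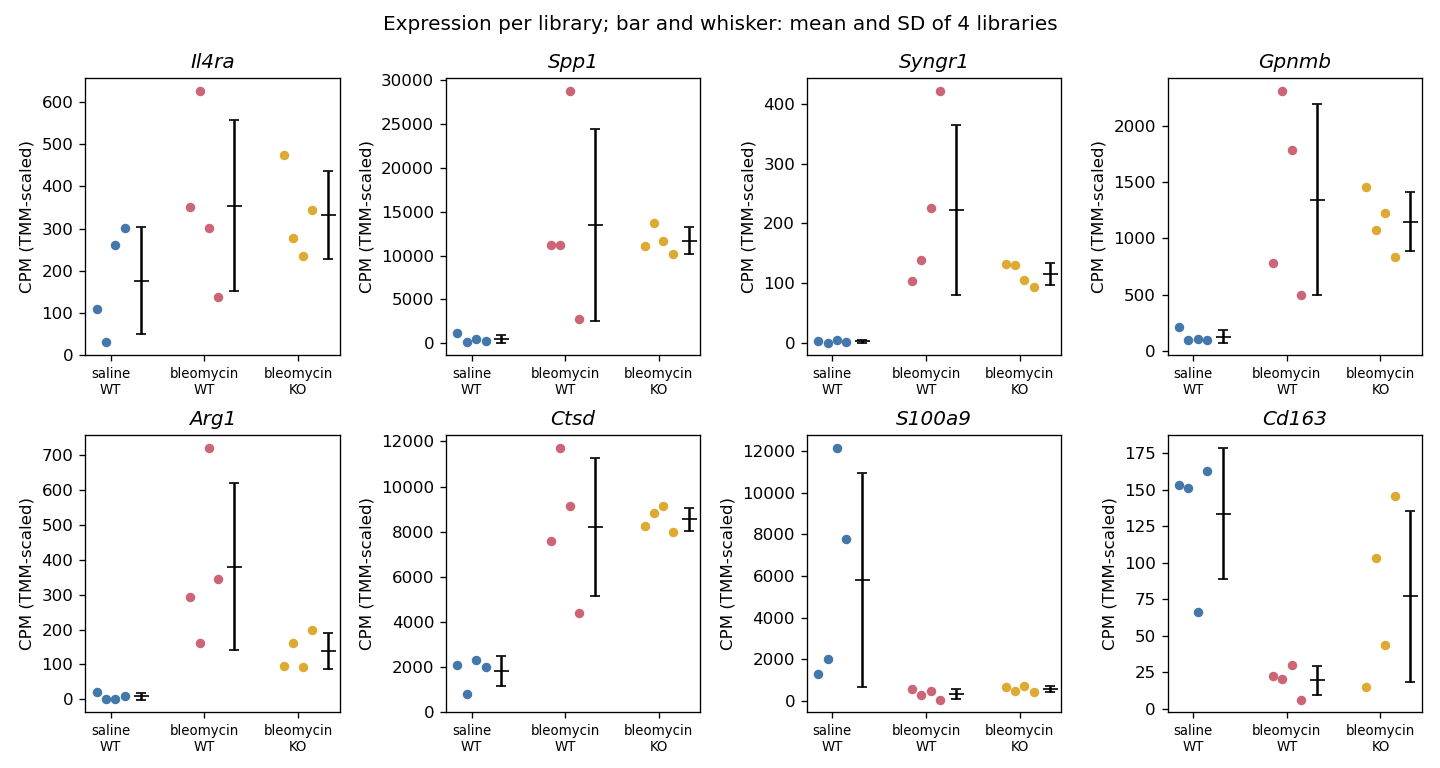
Expression of 8 genes in CPM, scaled by TMM, in each library of the 3 groups; points are single libraries, and the bar and whisker beside them give the mean and SD of 4 libraries. All saline libraries lie below all bleomycin WT libraries for Spp1, Syngr1, Gpnmb, Arg1 and Ctsd, and above them for S100a9 and Cd163, while Il4ra overlaps between all groups.

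The second comparison asks what the Il4ra deletion changed among bleomycin-treated animals. No named gene passed. Arg1 was 137 ± 51.4 CPM in KO and 380 ± 240 CPM in WT (SD, n = 4 each), a log2 fold change of -1.47 (SE 0.76, edgeR adjusted p 0.9998), and the libraries of the groups overlapped. Ccl4, a chemokine, was 589 ± 149 against 288 ± 170 CPM (log2 fold change 1.03, SE 0.46), and Cxcl10, an interferon-induced chemokine, was 254 ± 35.7 against 141 ± 56.3 CPM (log2 fold change 0.84, SE 0.55), with all 4 KO libraries above all 4 WT libraries for Cxcl10. Cd163 was 77.0 ± 58.8 against 19.5 ± 9.84 CPM (log2 fold change 1.98, SE 0.69, edgeR adjusted p 0.949). Spp1 and Syngr1 were above their saline levels in the libraries labelled KO, as given under the third comparison.

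Of 16679 genes 0 passed with edgeR (smallest adjusted p 0.934), and 0 passed with DESeq2, limma-voom or limma-voom with quality weights; 647 had an unadjusted p under 0.05, fewer than the 834 that chance gives. Of those, 616 were lower in KO and 31 higher. Without bleomycin WT 4 the number at an unadjusted p under 0.05 was 149. Among the named genes, those with the most negative values, Maf, Abcg1 and Bhlhe41, were far higher in that library than in the other WT libraries. Maf, a transcription factor, was 3353 CPM in bleomycin WT 4 and 30.6 to 42.1 CPM in the other 3 WT libraries. Its log2 fold change of -4.70 with 12 libraries was -0.09 without saline WT 2 and bleomycin WT 4. Igf1, insulin-like growth factor 1, was 2265 CPM in bleomycin WT 4, and its value went from -1.68 to 0.00. Abcg1 and Bhlhe41, both of the alveolar macrophage list, went from -4.08 to -0.42 and from -3.81 to -0.23.

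Inflammatory and interferon genes were higher in KO as lists with the preset correlation, by small amounts. Inflammatory cytokines and chemokines had a median log2 difference of 0.43, with 19 of 24 members higher (camera adjusted p 0.00172), and interferon-stimulated genes of 0.52, with 19 of 26 higher (0.00591). Non-classical monocyte genes (median 0.41, 0.0380) and cell cycle genes (median 0.17, 0.0331) also passed. With an estimated correlation none of the 4 lists passed (adjusted p = 0.955 for each), fry gave an adjusted p of 0.959 for each, and 0 members of any list passed over all genes or over the list alone. Without bleomycin KO 1 the number of lists that passed was 1, and without bleomycin KO 2 it was 2.

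Without saline WT 2 and bleomycin WT 4 the medians were 0.38 for the inflammatory list, with 22 of 24 members higher (camera adjusted p 1.2e-11, and adjusted p = 0.160 with an estimated correlation), and 0.36 for the interferon list (0.000127, and adjusted p = 0.441 with an estimated correlation). MHC class II genes had a median of 0.27 there, with all 13 members higher (camera adjusted p 2.0e-06, and adjusted p = 0.732 with an estimated correlation); in 12 libraries the median was 0.27 (camera adjusted p 0.0780). H2-Eb1, a class II chain, was 2966 ± 587 in KO against 2116 ± 879 CPM in WT in the 12 libraries. In the 10 libraries non-classical monocyte genes (median 0.24, camera adjusted p 0.00125) and interstitial macrophage identity genes (median 0.11, camera adjusted p 0.0353) also passed as higher. With an estimated correlation neither did (adjusted p = 0.732 for each). Cell cycle genes no longer passed in the 10 libraries (median -0.11, camera adjusted p 0.904). The sign of their median turned, while camera still placed them on the higher side.

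Lists tied to IL-4 and to fibrosis did not pass. The list induced by IL-4 and IL-13 had a median of 0.09 with 14 members higher and 12 lower (camera adjusted p 0.738), the receptor pathway 0.11 (0.690), the fibrosis-associated list -0.09 (0.868) and the secreted mediators -0.13 (0.704). Vegfa was 92.7 ± 49.8 against 220 ± 134 CPM, Klf4 53.9 ± 36.2 against 104 ± 59.2 CPM, and Cish 81.8 ± 25.6 against 121 ± 81.4 CPM. In the 12 libraries alveolar macrophage identity (0.13, 0.738), interstitial macrophage identity (-0.03, 0.616), classical monocyte genes (0.10, 0.256), MHC class II genes, cholesterol biosynthesis (0.11, 0.616), lysosome (0.01, 0.868), glycolysis and hypoxia (-0.08, 0.877), fatty acid oxidation (0.02, 0.830) and complement and scavenger receptors (-0.03, 0.848) did not pass either, values being the median log2 difference and the camera adjusted p. Camera's side and the sign of the median differed for the interstitial, lysosome, glycolysis and complement lists.

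No list of other cell types passed between KO and WT: neutrophil genes (median 0.30, camera adjusted p 0.261), eosinophil, basophil and mast cell genes (0.34, 0.775), dendritic cell genes (0.46, 0.397), T and NK cell genes (0.06, 0.838), B and plasma cell genes (-0.49, 0.775), lung epithelium (-0.32, 0.830), endothelium (0.20, 0.848), fibroblast and smooth muscle genes (0.18, 0.397), erythroid and platelet genes (1.08, 0.171) and dissociation and stress genes (0.05, 0.422). Camera placed the endothelium list on the lower side although its median was above 0. S100a9 was 570 ± 145 in KO and 343 ± 236 CPM in WT, and Col3a1 was 115 ± 83.5 and 116 ± 25.0 CPM.

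**Figure D3:**
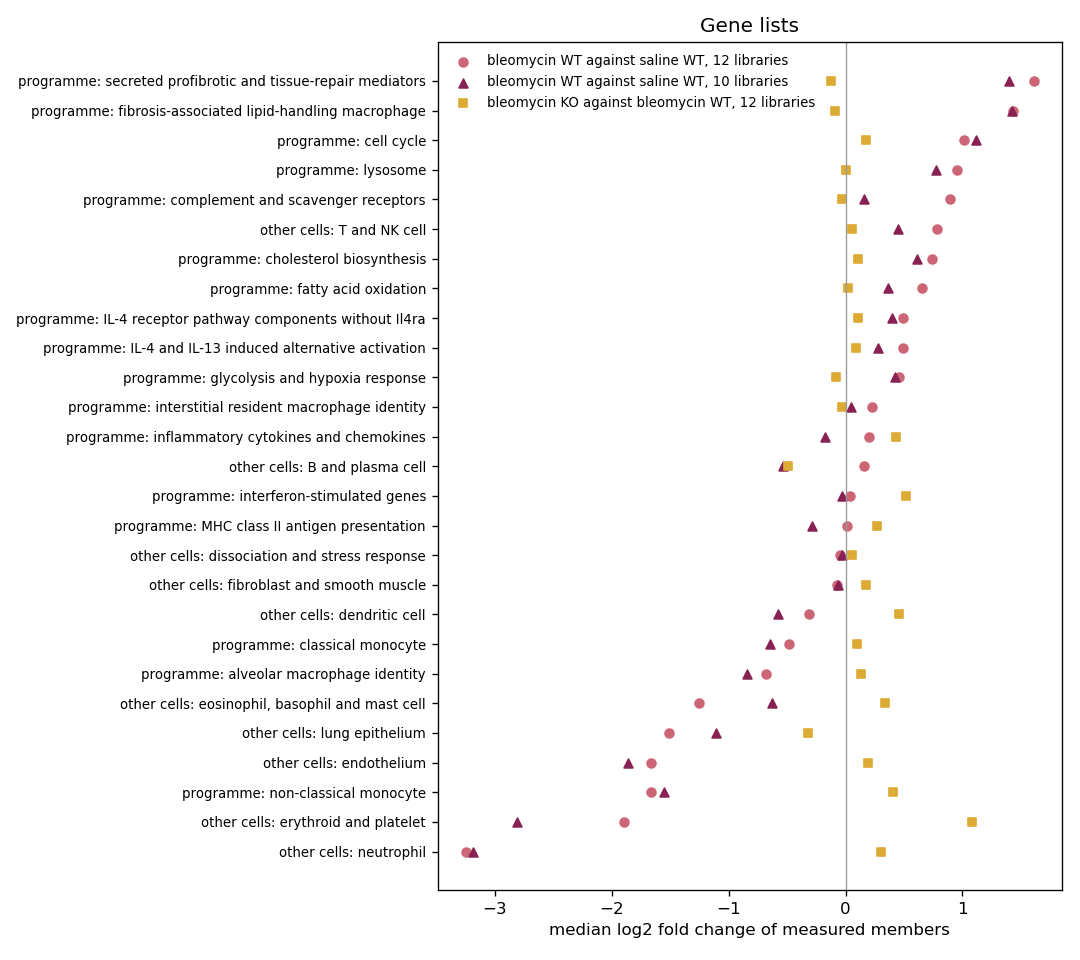
Median log2 fold change of the measured members of each of the 27 gene lists (rows) for bleomycin WT against saline WT with 12 libraries and with 10 libraries, and for bleomycin KO against bleomycin WT with 12 libraries. The neutrophil list lies lowest for bleomycin WT against saline WT (median -3.25) and the secreted mediators highest (1.61).

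The third comparison, bleomycin KO against saline WT, differs in treatment and genotype together and shares libraries with both others. As in the first comparison, library quality differed between the groups as well. Slc6a8, Syngr1 and Spp1 rose, with all 4 KO libraries above all 4 saline libraries for Syngr1 and Spp1, and above saline WT 1, 3 and 4 for Slc6a8. Spp1 was 11679 ± 1527 CPM in KO (SD, n = 4; log2 fold change 4.50, SE 0.69, edgeR adjusted p 0.0437) and Syngr1 115 ± 19.0 CPM (log2 fold change 5.10, SE 0.66, edgeR adjusted p 0.0162). Slc6a8 had 867 counts in KO, a ratio of 171 to saline WT with an exact interval of 47.3 to 1417 (edgeR adjusted p 0.0437). Gpnmb had a log2 fold change of 3.16 and an edgeR adjusted p of 0.0733. These 3 were the genes that passed, and 0 fell. An unadjusted edgeR p under 0.05 was found for 1506 genes, of which 493 were higher and 1013 lower. DESeq2 gave 370 genes (88 higher, 282 lower), limma-voom with quality weights 232 (87 higher, 145 lower), and limma-voom 12 (6 higher, 6 lower). The edgeR count was 0 without saline WT 3, saline WT 4, bleomycin KO 1 or bleomycin KO 2, 1 without saline WT 1, bleomycin WT 1, bleomycin WT 2, bleomycin KO 3 or bleomycin KO 4, 10 without saline WT 2 and 18 without bleomycin WT 4.

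Without saline WT 2 and bleomycin WT 4, 71 genes rose and 50 fell in the third comparison. Both comparisons use the same saline libraries, so their gene lists are not independent. Ctsd was 8612 ± 571 CPM in KO (SD, n = 4) there, Apoe 28103 ± 4392 CPM, and Il1rn, the IL-1 receptor antagonist, 1296 ± 124 CPM against 459 ± 35.5 CPM in saline WT (SD, n = 3).

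The log2 fold changes of the first and second comparisons correlated negatively across the 16679 genes (r = -0.434, covariance -0.687), and genes are not independent replicates. The bleomycin WT libraries enter both with opposite sign. In 10 simulations of unchanged groups r averaged -0.473 and the covariance -0.485. When the bleomycin WT libraries were split 2 and 2 so that the comparisons shared none, the mean over the 6 splits was -0.0132, with a range of -0.171 to 0.175, and the covariance averaged -0.0205. No gene passed in both comparisons, since 0 passed in the second.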

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

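Values were flagged where 1 of the 4 libraries of a group lay far from the other 3. Among 21 groups of quality values 2 were flagged, and among 225 groups of gene values (75 named genes in 3 groups) 31, of which 16 were high values in bleomycin WT 4. Many of these genes were named through a contrast that includes bleomycin WT 4, so the number is not set against chance. The splits of the 8 libraries of each comparison were planned in advance, but what each outcome would mean was written down after they had been run; the splits with 10 libraries and all tests of the 3 patterns were chosen after the results were seen. The explanation by bleomycin WT 4 alone was formed from the same counts it is set against, and its test was later tightened. It took the place of a comparison of the biological coefficient of variation (0.862 with 12 libraries, 0.775 with 10), whose limits had also been set afterwards.

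The highest Spearman correlation with another library was low in bleomycin WT 4 (0.730) and high in bleomycin KO 1 (0.986). The genes high in bleomycin WT 4 were Maf (3353 CPM), Abcg1 (7171), Bhlhe41 (1350), Igf1 (2265), Ctsz (6649), Mitf (573), Hk2 (694), Hdc (717), Cd93 (696), Calcrl (477), Pmvk (328), Eci1 (326), Lck (260), Ptprb (221), Tpx2 (219) and Gbp5 (199 CPM). In saline WT, 1 library was far off for Gpnmb (210 CPM in saline WT 1), Tpx2 (89.0 CPM in saline WT 1), Cd163 (66.5 CPM in saline WT 3), and Maf (173), Mitf (141) and Itga2b (21.6 CPM, only 2 counts) in saline WT 2. In bleomycin WT the others were Ccr7 (167 CPM in bleomycin WT 3) and Scgb1a1 (360 CPM in bleomycin WT 1). In bleomycin KO they were Klf4 (108), Cd93 (95.9) and Maf (25.1 CPM) in KO 1, Itga2b (10.2 CPM) in KO 2, Il6 (173 CPM) in KO 3, and Eci1 (47.3) and Gbp5 (5.13 CPM) in KO 4.

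The first pattern is that few genes passed between bleomycin WT and saline WT with all 12 libraries. Each pair of 1 saline and 1 bleomycin WT library was left out in turn. The pairs that held bleomycin WT 4 gave at least 15 genes and at most 119, and the 12 pairs without it at most 3. Leaving out bleomycin WT 4 by itself gave 11, fewer than any pair that held it, so whether it widens the spread alone stays open. Leaving out saline WT 2 with it gave 81 genes, and 1 of the other 15 pairs, saline WT 1 with bleomycin WT 4, gave as many; without all 3 libraries it was 522. The part of saline WT 2 cannot be told apart from that of saline WT 1 with these libraries. What sets bleomycin WT 4 apart, a technical fault or a difference between animals, stays open, and no biological explanation was tested because the labels name no other difference.

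The second pattern is that bleomycin WT 2 and bleomycin KO 1, of different genotype labels, deviated together from the mean of the other bleomycin libraries (bleomycin WT 4 not included; r = 0.861 across 8993 genes, against at most 0.367 in the other 20 pairs). A shared trend with gene length was present (Spearman correlation with length 0.490 and 0.528), but after removing trends on gene length and GC content r was 0.772, against at most 0.291 in the other pairs, which argues against those trends as the whole source. A single library deposited as both is argued against by a chi-square of 31.7 per degree of freedom between their counts. Preparation in 1 batch stays open, since the labels give none, and no biological explanation was tested.

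The third pattern is that Il4ra was not lower in the libraries labelled KO. An exchange of KO and WT labels, with a deletion that removes the counted transcript, would leave at least 1 bleomycin library with little Il4ra; the lowest held 138 CPM, where 0.1 of the saline mean is 17.7 CPM. A deletion that leaves most of the transcript in the count cannot be told apart from an intact gene here, since the log2 fold change of -0.0933 is of the whole gene and counts per exon were not analysed here. Receptor signal kept in these libraries cannot be told apart from lost signal either: the IL-4 and IL-13 induced list had a median of 0.0932 (camera adjusted p = 0.955 with an estimated correlation), with members on both sides. A deletion in only part of the sorted cells is untested.

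Other splits of the same libraries bear on the counts of genes. With 12 libraries, 1 of 35 splits gave as many genes as the real 4 in bleomycin WT against saline WT (the highest other gave 3) and 1 of 35 as many as the real 3 in bleomycin KO against saline WT (highest other 0). In the first of these the margin over the next split was 1 gene, and the count fell to 1 or 2 without most single libraries and to 0 with only the 8 libraries compared, so the split count there is weak evidence against chance. In bleomycin KO against saline WT the count fell to 0 or 1 without most single libraries and to 1 with only the 8 libraries compared. The split count is weak evidence there too. In bleomycin KO against bleomycin WT the real count was 0 (highest other 0), so that all 35 splits gave as many was fixed in advance and tests nothing. Without saline WT 2 and bleomycin WT 4, 1 of 35 splits gave as many as the real 121 in bleomycin KO against saline WT (highest other 0); in bleomycin KO against bleomycin WT the real count was again 0 and all 35 splits had to give as many. For bleomycin WT against saline WT 10 splits are too few for a share under 0.05; the real value was 81 and the highest other 0.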

How the results depend on the processing

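The fits without saline WT 2 and bleomycin WT 4, without these and saline WT 1, and without bleomycin WT 2 and bleomycin KO 1 were chosen after the data were seen. For bleomycin WT against saline WT, 4 genes passed in edgeR; the count was 1 at an adjusted p under 0.01, with DESeq2 size factors and with upper-quartile scaling, 780 (358 higher, 422 lower) without a filter, 512 (181 higher, 331 lower) with DESeq2, 319 (150 higher, 169 lower) with limma-voom quality weights, 6 with limma-voom, 0 with only the 8 libraries compared, and 1 to 11 with 1 library left out. It was 81 without the 2 libraries, 522 without 3 and 1 without bleomycin WT 2 and bleomycin KO 1. For bleomycin KO against bleomycin WT the count was 0 in all alternatives except the fit without a filter, which gave 243 (1 higher, 242 lower). For bleomycin KO against saline WT the 3 genes became 0 at an adjusted p under 0.01, 1 with DESeq2 size factors, upper-quartile scaling or only the 8 libraries, 694 without a filter (68 higher, 626 lower), 370 with DESeq2 (88 higher, 282 lower), 12 with limma-voom, 232 with quality weights (87 higher, 145 lower), 0 to 18 with 1 library left out, 121, 465 and 0 in the 3 added fits. The cause was not tested for any of these.

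Syngr1 passed in 23 of 24 alternatives for bleomycin WT against saline WT, Spp1 in 14, Gpnmb in 8 and Slc6a8 in 6, all with a positive log2 fold change. Scaling moved the share of higher genes among those at an unadjusted p under 0.05 from 57.8% to 45.1% with DESeq2 size factors and 30.9% with upper-quartile scaling in that comparison, and from 32.7% to 23.8% and 18.3% in bleomycin KO against saline WT.

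In bleomycin WT against saline WT 16 lists passed (9 higher, 7 lower), 12 with the stricter filter (4 higher, 8 lower, 10 of them among the 16), 2 with an estimated correlation and 6 with fry; the fibrosis-associated list and the secreted mediators passed in all 20 alternatives. The IL-4 and IL-13 induced list passed in 12 of these 20 alternatives, and glycolysis and hypoxia response in 10. In bleomycin KO against bleomycin WT 4 lists passed, 0 with an estimated correlation or fry, and 1 to 6 with 1 library left out. The number was 5 without saline WT 2 and bleomycin WT 4, and 5 without these and saline WT 1. It was 6 (5 higher, 1 lower) without bleomycin WT 2 and bleomycin KO 1. For Il4ra the log2 fold change of KO against WT was -0.08 with DESeq2 size factors, -0.35 without saline WT 2 and bleomycin WT 4, and from -0.38 to 0.34 over all 24 alternatives, with a changed sign in 3. The correlation between the first pair of comparisons was -0.616 with the stricter filter, -0.607 to -0.189 with 1 library left out and -0.0132 with the bleomycin WT libraries split. No named gene that passed in either fit and no list that passed in both changed direction. Values that did not pass changed sign in some alternatives, and so did the median of the cell cycle list in bleomycin KO against bleomycin WT.

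No pairing of libraries by replicate number was seen: same-number deviations correlated between -0.202 and 0.0665, and in 1 of 12 tests a library correlated best with its own number. Low correlations do not exclude a pairing. With the replicate block 2 genes passed in bleomycin WT against saline WT, 0 in bleomycin KO against bleomycin WT and 1 in bleomycin KO against saline WT. No sex covariate was fitted, because all libraries show Y-linked and little Xist expression. Simulated 4-fold changes were mostly missed in all 3 comparisons.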

Other observations

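The 81 genes of the fit without saline WT 2 and bleomycin WT 4 include the genes below, named here after their values were seen. Acp5, tartrate-resistant acid phosphatase, was 420 ± 34.3 in bleomycin WT against 139 ± 32.1 CPM in saline WT (SD, n = 3 each; edgeR adjusted p 0.0169). Osm, the cytokine oncostatin M, was 1119 ± 204 against 396 ± 89.8 CPM (edgeR adjusted p 0.0478). In KO Osm was 960 ± 233 CPM (SD, n = 4; edgeR adjusted p 0.0558 against saline WT), and KO against WT did not pass (log2 fold change -0.22, edgeR adjusted p 0.99993).

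Genes lower in bleomycin WT in that fit include Acod1, the enzyme that makes itaconate, at 90.6 ± 27.6 against 929 ± 573 CPM (edgeR adjusted p 0.0217), Treml4 at 21.5 ± 7.40 against 289 ± 135 CPM, and S1pr5, a sphingosine phosphate receptor, at 4.40 ± 1.65 against 48.6 ± 12.9 CPM (edgeR adjusted p 0.0169). In the libraries labelled KO Acod1 was 123 ± 10.2 CPM and S1pr5 4.05 ± 0.97 CPM (SD, n = 4). S100a9 of the neutrophil list fell in the same fit, and the levels of S100a9 in saline WT 3 and saline WT 4 were 12140 and 7791 CPM.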
